A study of Homo sapiens with 21 samples.

How the data were processed

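RNA was measured by poly(A)-selected RNA sequencing in 21 libraries of BJ cells, a human skin fibroblast line of limited replicative lifespan. The labels give 7 groups of 3 libraries: cells at passages P3, P11, P24, P30 and P33, and P11 cells given either DOX at 50 ng/ml (doxorubicin, per the series title) or DMSO, the solvent control. Per the labels' protocols, RNA was primed with random hexamers after poly(A) selection, the first strand was ligated to an adaptor and amplified by 18 PCR cycles, and paired reads were taken on a DNBSEQ-T7. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

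The deposited table holds whole-number read counts per gene, made by the authors and not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.9, cutadapt 3.3, HISAT2 2.1.0, SAMtools 1.11, Subread with featureCounts 2.0.1 and DESeq2 1.34.0, and the builds named were hg38 and GRCh38.p13. Options of these tools are not given in the sources used here. The table lists 61544 genes with coordinates on that build, and the length it gives for each equals the whole span from start to end, introns included. Totals per library ran from 12.946 to 27.194 M counts. A floor of 3 counts, used for groups at 0, was summed over the 3 libraries of a group. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

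The table was not counted alike in its 2 parts. Of 9429 genes that lie wholly inside another gene on the same strand, none had a read in the 15 passage libraries, while 3950 had reads in the 6 DOX and DMSO libraries, 684919 reads in all. Of 10950 genes that lie inside a gene of the opposite strand and not inside one of their own strand, 4260 and 3989 had reads in the passage and in the DOX and DMSO libraries. Genes that overlap another gene on the same strand (5966 of those tested, 510 of them wholly inside) are therefore uncertain wherever both parts meet. The strand setting of the counting is not given in the sources used here. Had strand been ignored in the passage libraries, genes inside an opposite-strand gene would have been empty like those inside a same-strand one. The 4260 with reads there argue against that. For the DOX and DMSO libraries the setting stays open, and reads carried to the wrong strand were not measured. Comparisons within a part, and the difference of 2 within-part effects, do not set one part's level against the other's.

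Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 16821 genes and took 44723 out. Libraries were scaled with TMM (factors 0.899 to 1.13), and 1 quasi-likelihood model with a mean per group was fitted to all 21 libraries, with 14 residual degrees of freedom and a biological coefficient of variation of 5.48%. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 16821 genes, and a gene was said to rise or fall at an adjusted p under 0.05. Levels are CPM on TMM-scaled library sizes, as mean ± SD of 3 libraries, and log2 fold changes carry their standard error (SE). There were 11 comparisons: P11, P24, P30 and P33 each with P3, the steps P24 with P11, P30 with P24 and P33 with P30, P33 with P11, DOX with DMSO, DMSO with untreated P11, and the difference between the DOX effect and the P33 effect. No replicate block was used.

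Gene groups were tested with camera on voom values (preset correlation 0.01, and again with an estimated correlation), adjusted over the 27 lists within a comparison. Some list members lie wholly inside another gene on the same strand, RPS10, IFITM1, TIGAR and TEN1 among them. Such members had no reads in the passage libraries, and those that passed the count filter entered the passage comparisons as unchanged genes. The lists, samples, tests, alternatives and the rule for named genes were chosen before the data were examined. List tests for P33 with P30 and P33 with P11 were not among those planned. The rule took, for P33 with P3, DOX with DMSO and their difference, a core senescence panel of 15 genes, the 5 largest rises and 5 largest falls among protein-coding genes that passed, had at least 5 CPM in the higher group and did not overlap between the groups' replicates (no overlap rule for the difference), and up to 3 members of each list that passed. For the other comparisons it took the 3 largest rises and 3 largest falls.

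The fit was tested on simulated counts with 200 changed genes: it recovered 78% of 2-fold and 95% of 4-fold changes for P33 with P3, with 5.46% of calls false. For DOX with DMSO the shares were 80%, 95% and 3.85%, and for the difference 64%, 88% and 7.88%, each over 16821 genes. In the simulated list test 1 list was changed by 1.5-fold and called, and 1 of 26 other lists was called as well. Simulated genes were drawn independently of each other, so this does not cover correlation among list members. That correlation was estimated at 0.628 for interferon-stimulated genes at P33 against P3. Only 200 genes were changed, against 11408 called in that comparison, so the false shares need not carry over.

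Alternatives were RLE scaling, no count filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, a fit of the compared groups alone, the replicate number as a block, leaving out each library in turn, a 2-fold minimum, P33 with P11 as baseline, and camera with an estimated correlation. Chosen after seeing the data were fits without genes that overlap on the same strand, without mitochondrially encoded genes, and overlaps without cell cycle, histone, repair and chromatin lists. Gene lengths and GC content used in the closing tests came from a human reference annotation whose build may differ from the authors'. Genes of X inactivation and of the Y chromosome were not reported. Some genes that the rule for named genes took are not reported here, while counts over lists include them.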

Results

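Gene expression was measured in BJ human skin fibroblasts carried from passage P3 to P33, a course at the end of which fibroblasts enter replicative senescence, and in P11 cells given doxorubicin (DOX, a topoisomerase poison that breaks DNA) at 50 ng/ml or the solvent DMSO. The series title names the question as what replicative and doxorubicin-induced senescence share. Each of the 7 groups had 3 libraries. Totals were 20.886 to 26.35 M counts at P3, 15.001 to 18.994 at P11, 16.912 to 21.867 at P24, 12.946 to 19.066 at P30, 18.418 to 21.361 at P33, 21.678 to 27.194 with DOX and 18.174 to 24.654 with DMSO. Values are CPM (counts scaled to library size) as mean ± SD of 3 libraries unless another error is named.

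Libraries of one group lay close together, and the largest axis parted the DOX and DMSO libraries from all passage libraries. The components used all tested genes, among them 510 wholly inside another gene that had no reads in the passage libraries. The difference of counting between the parts therefore enters the largest axis, by a share that was not measured. This largest component held 73.9% of the variance, and the next, with 10.7%, placed the passages in order from P3 (libraries between -55.32 and -54.16) to P33 (57.65 to 60.53). DOX libraries lay at 19.7 to 20.74 on it and DMSO libraries at -15.81 to -13.4. In the passage libraries alone the first component held 48.6% of the variance and ran in passage order, while the second, with 15.5%, set P30 apart from P33.

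**Figure D1:**
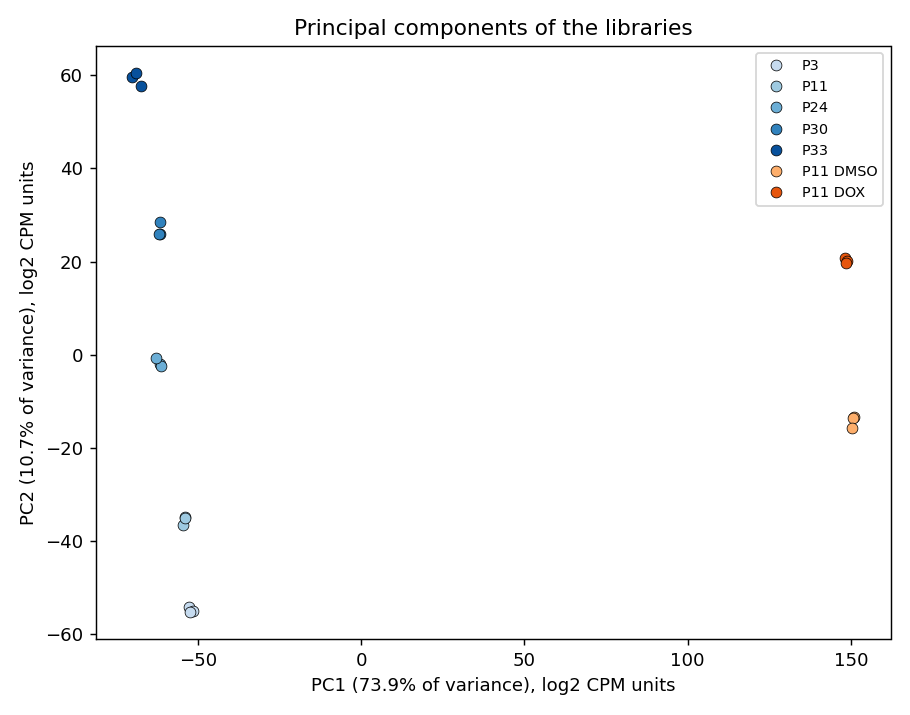
Principal components 1 (x axis, 73.9% of variance) and 2 (y axis, 10.7%) of log2 CPM over the tested genes, 1 point per library, coloured by group. Component 1 parts the 6 DOX and DMSO libraries from the 15 passage libraries, which were not counted alike, and component 2 runs from P3 to P33.

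Late passage was compared with early passage to find what changed as the cells approached the end of their lifespan. At P33 against P3, proliferation genes were lower. Interferon-response and stress-response transcripts were higher, as were histone transcripts in this poly(A)-selected RNA. Lower levels were seen for mRNAs of ribosomal proteins and cholesterol enzymes. The interferon and ribosomal protein list calls were lost with an estimated correlation (adjusted p = 0.323 and 0.0706 with an estimated correlation). MKI67, a marker of cycling cells, fell from 510 ± 41 to 153 ± 4.6 CPM (log2 fold change -1.74, SE 0.0765). LMNB1, the nuclear lamina protein whose loss marks senescent cells, fell from 44.4 ± 2.8 to 15 ± 0.42 CPM. CDKN1A, the p53-induced inhibitor p21, rose 1.46-fold, from 198 ± 6.2 to 289 ± 1.2 CPM. Of 16821 genes tested, 11408 passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 5801 higher and 5607 lower, and 2473 rose and 1083 fell by at least 2-fold.

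The core senescence panel moved in both directions. Of its 15 genes 7 rose, 6 fell and 2 did not pass, the same counts when adjusted over the list alone, and the panel as a whole was not called (adjusted p = 0.671). CDKN2B, encoding the inhibitor p15, rose 3.54-fold to 42.9 ± 8 CPM, whereas CDKN2A, encoding p16 and ARF, fell 1.4-fold, from 16.6 ± 1.6 to 11.8 ± 1.6 CPM (adjusted p = 0.000234). CXCL8, the chemokine IL-8, rose from 0.422 ± 0.072 to 5.02 ± 1.2 CPM and IL6 from 4.08 ± 0.86 to 6.77 ± 1.6 CPM. GDF15, a stress-induced cytokine, rose 5.23-fold. RB1 fell 1.23-fold, and the chromatin proteins HMGB1 and HMGB2 fell 1.85-fold and 1.87-fold. GLB1, the lysosomal beta-galactosidase, had a log2 difference of 0.10 (SE 0.0605, adjusted p = 0.161), and TP53BP1 one of 0.05 (SE 0.0566), but with the 10 CPM filter both passed, at 0.2214 and 0.1798 (adjusted p = 0.00141 and 0.00486). RB1, HMGB1, GLB1 and GDF15 overlap another gene on the same strand, so part of their reads may have been assigned elsewhere.

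Cell cycle groups fell together. Of 43 S phase genes 37 fell and 1 rose (38 and 1 adjusted over the list alone; camera adjusted p = 2.4e-08), and of 53 G2 and M phase genes 50 fell and 2 rose in both counts (adjusted p = 2.74e-17). The replication helicase subunit MCM2 fell 2.65-fold to 28.9 ± 0.091 CPM, CDCA7 3.26-fold and GINS2 2.57-fold, and the mitotic genes CDC20 and DLGAP5 fell 3.74-fold and 3.3-fold. In the homologous recombination and Fanconi repair list 18 of 30 genes fell and 4 rose (adjusted p = 0.0478; adjusted p = 0.226 with an estimated correlation), among them BLM and FANCE, which fell 1.87-fold and 1.76-fold. That list call was also lost without P3 replicate 1, P33 replicate 2 or P33 replicate 3 (adjusted p = 0.0656, 0.0729 and 0.0554). Of 28 nuclear envelope and chromatin genes 24 fell and 2 rose (25 and 2 over the list alone; adjusted p = 3.47e-08), with LMNA falling from 1680 ± 50 to 685 ± 38 CPM and HMGB3 2.28-fold. Replication-dependent histone genes, whose mRNAs normally end without a poly(A) tail, went the other way: 21 of 22 rose in both counts and none fell (adjusted p = 7.18e-07). H4C8 rose 6.13-fold to 45.8 ± 2.1 CPM and H2BC21 5.22-fold, and H2BC18, which overlaps another gene, rose 11.5-fold. Histone genes are near-identical copies of each other, so the share of each is uncertain. Of 58 listed histone genes 22 passed the count filter. The RNA was poly(A)-selected, so histone counts here and in every other comparison come mainly from transcripts with a tail. Total histone mRNA was not measured. The S phase, G2 and M phase, histone and nuclear envelope calls held with an estimated correlation (adjusted p = 0.0305, 0.0403, 0.0155 and 0.0305).

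Genes of the p53 response and of secreted factors were mostly higher. Of 42 p53 targets 29 rose and 7 fell (adjusted p = 1.03e-05, 0.0305 with an estimated correlation), including ACER2, an alkaline ceramidase, by 3.03-fold and SESN2 by 2.7-fold. Of 41 secreted cytokines and growth factors of the senescence-associated secretory phenotype (SASP) 28 rose and 7 fell (adjusted p = 0.000123, but adjusted p = 0.246 with an estimated correlation). IL1A rose 21.1-fold to 7.42 ± 1.1 CPM, while the chemokine CXCL12 fell 11.8-fold, from 202 ± 3.3 to 17.1 ± 1.9 CPM. Secreted proteases and inhibitors went both ways, 8 up and 12 down of 25 (adjusted p = 0.656): PLAT, tissue plasminogen activator, rose from 91 ± 4.5 to 967 ± 8.2 CPM and TIMP3 2.93-fold, and the collagenase MMP1 fell from 1320 ± 66 to 278 ± 28 CPM. Of 6 IGF-binding proteins 5 rose and 1 fell (adjusted p = 0.00539; adjusted p = 0.0844 with an estimated correlation), with IGFBP5 at 9270 ± 310 CPM against 1980 ± 52 and IGFBP3 and IGFBP2 up 2.83-fold and 2.61-fold. All counts in this list group were the same when adjusted over the list alone.

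Interferon-stimulated genes rose almost throughout: 39 of 46 rose and 1 fell (39 and 2 over the list alone), with a median log2 fold change of 1.45 (adjusted p = 1.77e-08). The call was lost when the correlation among these genes was estimated (adjusted p = 0.323 with an estimated correlation). The antiviral genes RSAD2, IFI44L and OAS1 rose 18.1-fold, 14.9-fold and 12.3-fold, IFI44L from 7.78 ± 1.8 to 115 ± 14 CPM. Stress-response lists rose as well. Of 26 NRF2 targets 18 rose and 3 fell (adjusted p = 0.00244), led by the cystine transporter SLC7A11, from 20.6 ± 1.3 to 187 ± 7 CPM, with GCLM up 2.94-fold and AKR1B1 2.36-fold. Of 34 genes of the unfolded protein and integrated stress response 25 rose and 7 fell (adjusted p = 2.76e-05), with ATF3 up 9.87-fold, TRIB3 6.51-fold and PSAT1, a serine synthesis enzyme, 6.01-fold. Both stress lists kept their calls with an estimated correlation (each at 0.0305), and their counts did not differ when adjusted over the list alone.

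Biosynthetic lists were lower. No gene of cholesterol synthesis rose and 20 of 25 fell (adjusted p = 5.74e-07, 0.0305 with an estimated correlation), with ACAT2 down 3.62-fold to 21.2 ± 1.6 CPM, and the sterol-regulated INSIG1 down 2.58-fold. Of 73 cytosolic ribosomal protein genes, a list kept as a check of RNA state, 67 fell and none rose (68 and 0 over the list alone), with a median of -0.94 (adjusted p = 8.11e-23; adjusted p = 0.0706 with an estimated correlation). RPS26 fell 3.11-fold, RPS21 2.83-fold and RPS7 2.69-fold, and ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Of 26 myofibroblast and TGF-beta response genes 16 fell and 6 rose (adjusted p = 0.014, 0.0305 with an estimated correlation, but 0.0791 without genes that overlap on the same strand, an alternative chosen after seeing the data), with the contractile genes MYL9, TAGLN and LMOD1 down 3.26-fold, 2.83-fold and 2.48-fold. Collagens and elastic fibre genes divided into 19 up and 27 down of 51 (20 and 28 over the list alone; adjusted p = 0.288), with COL15A1 up 7.42-fold, COL8A1 up 5.87-fold and COL11A1 down 4-fold. Lysosomal genes divided into 15 up and 18 down of 48 (16 and 18 over the list alone; adjusted p = 0.537), with LIPA down 2.46-fold and the cathepsins CTSS and CTSO up 2.37-fold and 2.3-fold. Of 16 shelterin and telomere genes 5 rose and 8 fell (adjusted p = 0.288), the telomerase RNP genes NOP10, NHP2 and DKC1 falling 2.32-fold, 2.18-fold and 1.74-fold.

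Of the lists kept as checks of sample make-up and RNA state, the ribosomal protein list was called at P33 against P3, as given above, and the others were not. Fibroblast identity genes were 4 up and 7 down of 14 (adjusted p = 0.0742, but called as lower without a count filter, 0.00202, and without P33 replicate 1, 0.0276), with VIM falling from 4240 ± 110 to 2310 ± 120 CPM, COL1A1 1.83-fold and S100A4 1.9-fold. Keratinocyte markers were 6 up and 1 down of 9 (adjusted p = 0.0851): CLDN1, a tight junction gene, rose 8.33-fold to 38.4 ± 6.6 CPM, KRT15 rose 1.77-fold and DSP fell 1.99-fold. Endothelial markers were 2 up of 5, leukocyte markers 2 up of 5, melanocyte and Schwann markers 1 up and 1 down of 4, and adipocyte and smooth muscle markers 4 down of 7 (adjusted p = 0.671, 0.537, 0.991 and 0.133). Mitochondrially encoded mRNAs were 3 up and 2 down of 13 (adjusted p = 0.671), the highest MT-ATP8, which overlaps MT-ATP6. Immediate early genes were 12 up and 5 down of 22 (adjusted p = 0.288), and FOS and FOSB at P33 had SDs near their means, 36.3 ± 34 and 23.2 ± 28 CPM. These other lists gave the same counts when adjusted over each list alone.

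Among the largest rises at P33 were genes near silence at P3. KLHDC7B on chromosome 22 (50545899 to 50551023, hg38) had no read at P3 and 6.53 ± 0.43 CPM at P33, at least 156-fold higher. LAMP3, a lysosome-associated membrane protein of dendritic cells, rose from 0.153 ± 0.04 to 33.3 ± 2.9 CPM, SLITRK6 to 10.3 ± 1.6 and the protocadherin PCDH1 to 9.23 ± 1.4 CPM, each from under 0.2 CPM. The largest falls were in GPAT2 (19.5-fold), C1orf115 (19-fold), CNTN3 (15.9-fold), PPP1R14A (14.4-fold) and EPB41L3, a cytoskeletal linker, from 96.3 ± 2.1 to 6.64 ± 1.5 CPM. Among the genes named above, COL11A1, TAGLN, S100A4, KRT15 and DKC1 overlap another gene on the same strand and are uncertain.

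**Figure D2:**
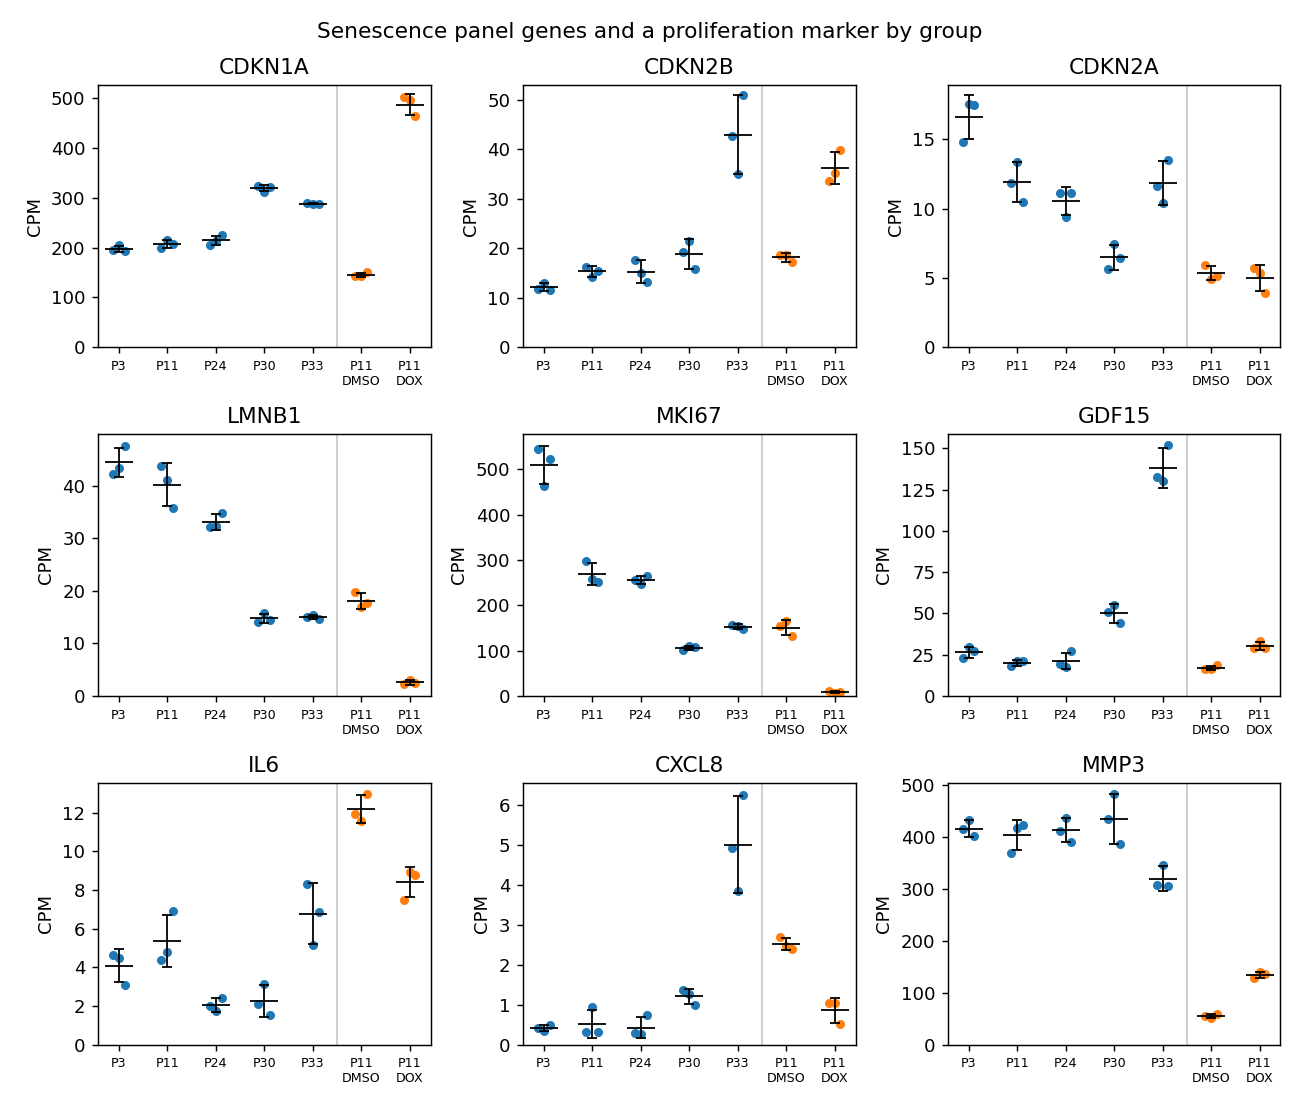
CPM (y axis, linear) of 9 senescence and proliferation genes in each library (points), with the mean and SD of each of the 7 groups (x axis); a grey line parts passage libraries from DMSO and DOX libraries. CDKN1A and CDKN2B are higher and LMNB1 and MKI67 lower at P33 than at P3 and with DOX than with DMSO.

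The earlier passages were compared with P3 to place these changes along the series. By P11 the G2 and M phase, secreted protease and myofibroblast lists were already lower and the cholesterol list higher. Secreted proteases and inhibitors fell in 13 of 25 and rose in 1 (14 and 1 over the list alone). Myofibroblast and TGF-beta response genes fell in 16 of 26 and rose in 3, also over the list alone. Both calls held (camera adjusted p = 6.47e-05 and 0.000324, 0.0149 each with an estimated correlation). MKI67 fell to 269 ± 25 CPM, and 45 of 53 G2 and M phase genes fell (45 over the list alone; adjusted p = 5.56e-18; adjusted p = 0.0614 with an estimated correlation). Of 25 cholesterol genes 21 rose and 1 fell (adjusted p = 4.17e-08, 0.0291 with an estimated correlation), opposite to P33. Interferon-stimulated genes rose in 27 of 46 (adjusted p = 0.000223; adjusted p = 0.677 with an estimated correlation), but replicates differed widely, with IFI44L at 33.5 ± 24 CPM, and without P11 replicate 2 the list was not called (adjusted p = 0.055). EGR1, a growth-factor-induced transcription factor, rose 4.94-fold and CLVS1 5.8-fold, and OLR1 and IL13RA2 fell 3.82-fold and 3.61-fold. MT-ATP8 rose 12.9-fold with an SD of 270 on 533 CPM, and EIF3CL, a near-copy of EIF3C, fell 4.3-fold, so both are uncertain. The P3 libraries also stood apart in make-up. Long noncoding RNAs held 0.95% of counts at P3 and 1.56%, 1.61%, 1.54% and 1.97% at P11, P24, P30 and P33. Whether passage or the P3 libraries themselves caused this was not tested. Ribosomal protein genes, kept as a check of RNA state, fell in 56 of 73 and rose in 2 (57 and 2 over the list alone; adjusted p = 1.19e-13; adjusted p = 0.236 with an estimated correlation). In all, 7825 genes passed (3852 higher, 3973 lower), 766 up and 231 down by at least 2-fold.

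At P24, 9150 genes differed from P3 (4476 higher, 4674 lower), and at P30, 9856 (4878 higher, 4978 lower), with 1311 up and 382 down by at least 2-fold at P24 and 1505 and 1080 at P30. ABCB1, the drug efflux pump P-glycoprotein, rose from 0.532 ± 0.14 CPM at P3 to 13.9 ± 0.57 at P24 and 24.1 ± 0.91 at P30. RUNDC3B, which overlaps ABCB1 on the opposite strand and could hold its wrong-strand reads, rose 21.4-fold and 43.5-fold. RSAD2 rose 14.1-fold at P24 and the junction protein JAM2 28.5-fold at P30. PENK and PRKG2 fell 5.28-fold and 5.12-fold at P24, and RGCC, NTM and NFE2L3 fell 14.2-fold, 12.2-fold and 11.2-fold at P30. Cell cycle genes reached their lowest passage level at P30, where 50 of 53 G2 and M phase genes had fallen (50 over the list alone) with a median of -1.55 (adjusted p = 4.64e-28, 0.0118 with an estimated correlation) and MKI67 stood at 106 ± 3.9 CPM. Ribosomal protein genes fell in 66 of 73 at P24 and 67 at P30 and rose in 1 each, also over the list alone (adjusted p = 3.3e-20 and 2.71e-16; adjusted p = 0.118 and 0.156 with an estimated correlation). Histone genes rose in 10 of 22 at P24 (10 over the list alone; adjusted p = 0.0135; adjusted p = 0.118 with an estimated correlation and 0.319 without a count filter) and in 16 of 22 at P30 (17 over the list alone; adjusted p = 2.42e-05, 0.0118 with an estimated correlation). The p53 target list was not called at P11, P24 or P30 (adjusted p = 0.83, 0.967 and 0.448). Without a count filter it was called as lower at P11 (median -0.04324, adjusted p = 0.0408).

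Steps between successive passages showed where single genes turned. From P11 to P24, 5658 genes passed, with JAM2 up 22.6-fold, ABCB1 19.1-fold and RUNDC3B 15.2-fold, and CYP1B1, PRKG2 and VAT1L down 5.96-fold, 4.87-fold and 4.85-fold. From P24 to P30, 5897 passed, with HAS3, a hyaluronan synthase, up 6.99-fold and RGCC, DENND2A and HAPLN1 down 14.1-fold, 10.9-fold and 9.7-fold. FOS and EGR1 also rose in that step, with wide spread at P30 (10.4 ± 7.9 and 189 ± 110 CPM). From P30 to P33, 8142 passed, with PAPPA2, SYT7 and ESM1 up 15.2-fold, 14.7-fold and 13.3-fold and SAMD11, TINAGL1 and ANO3 down 8.06-fold, 7.86-fold and 7.35-fold. In that step 28 of 43 S phase and 42 of 53 G2 and M phase genes rose (29 and 42 over the list alone; adjusted p = 3.35e-06 and 4.11e-11; adjusted p = 0.0688 and 0.104 with an estimated correlation), and MKI67 rose from 106 ± 3.9 to 153 ± 4.6 CPM. The p53 targets rose in 26 of 42 (27 over the list alone, adjusted p = 2.81e-07, 0.0132 with an estimated correlation), and LMNB1 did not pass (14.7 ± 0.9 and 15 ± 0.42 CPM). Of 14 lists called in this step 5 held with an estimated correlation, p53 targets among them. Repair genes rose in 21 of 30, proteases and inhibitors in 14 of 25 (4 fell) and stress response genes in 19 of 34 (2 fell). Myofibroblast and TGF-beta response genes fell in 16 of 26 (3 rose). Their camera adjusted p were 3.63e-06, 6.4e-05, 7.93e-07 and 3.63e-06 (0.0132, 0.0132, 0.0132 and 0.00218 with an estimated correlation). Check lists moved in the same step: ribosomal protein genes fell in 66 of 73, fibroblast identity genes in 9 of 14 with 2 rising, and adipocyte and smooth muscle markers in 2 of 7 (67, 10 and 2 falling over the list alone; adjusted p = 8.9e-16, 0.0005 and 0.0438; adjusted p = 0.131, 0.104 and 0.103 with an estimated correlation).

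With P11 in place of P3 as the baseline, 9655 genes passed at P33. PCDH1 was 254-fold higher (95% counting interval 69.9 to 2100, 2 reads at P11) and KLHDC7B 180-fold (49.5 to 1490, 2 reads), and PAPPA2 rose 133-fold. OLFML2A, CNTN3 and C1orf115 fell 23.7-fold, 21.1-fold and 18.4-fold. The myofibroblast and TGF-beta response list, lower at P33 against P3, was not called against P11. Of its 26 genes 11 rose and 13 fell, also over the list alone (median -0.1448, camera adjusted p = 0.611). All 22 histone genes rose in both counts (adjusted p = 1.43e-09, 0.00279 with an estimated correlation), 23 of 25 cholesterol genes fell, with none rising (adjusted p = 2.12e-14, 0.00363 with an estimated correlation), and 31 of 42 p53 targets rose and 3 fell (adjusted p = 7.95e-09, 0.00473 with an estimated correlation). Of the check lists, ribosomal protein genes fell in 68 of 73 with 1 rising and fibroblast identity genes in 8 of 14 with 2 rising, also over the list alone (adjusted p = 3.62e-19 and 0.0451; adjusted p = 0.132 and 0.37 with an estimated correlation).

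DOX was compared with DMSO in P11 cells to measure the response to DNA damage. Cell cycle genes fell, p53 targets rose, and so did histone genes in this poly(A)-selected RNA. Interferon-stimulated genes fell, a list call that was lost with an estimated correlation (adjusted p = 0.454 with an estimated correlation). MKI67 fell 17.2-fold, from 151 ± 17 to 8.7 ± 1.6 CPM, and LMNB1 7.07-fold, from 18.1 ± 1.5 to 2.59 ± 0.42 CPM. CDKN1A rose 3.36-fold, from 145 ± 4.2 to 488 ± 21 CPM. The largest rise was in CLCA2, a p53-induced chloride channel accessory protein, from 20.3 ± 0.39 to 167 ± 3.8 CPM. In all, 6278 genes passed, 2817 higher and 3461 lower, with 625 up and 594 down by at least 2-fold.

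Of the senescence panel 5 genes rose, 7 fell and 3 did not pass, the same counts over the list alone (adjusted p = 0.608 for the panel). CDKN2B rose 1.99-fold and GDF15 1.77-fold. HMGB2, HMGB1 and GLB1 fell 2.46-fold, 1.15-fold and 1.42-fold, and IL6 and CXCL8 fell 1.45-fold and 2.87-fold, from 12.2 ± 0.72 to 8.4 ± 0.78 CPM and from 2.53 ± 0.15 to 0.871 ± 0.31 CPM. CDKN2A was at 5.33 ± 0.52 and 4.99 ± 0.94 CPM (adjusted p = 0.679), RB1 at 89.6 ± 4.9 and 87.8 ± 7.7 CPM, and TP53BP1 at 240 ± 12 and 250 ± 19 CPM.

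Of 43 S phase genes 36 fell and 2 rose, and of 53 G2 and M phase genes 47 fell and 2 rose, both also over the list alone (adjusted p = 2.68e-17 and 3.45e-31, 0.00438 and 0.00584 with an estimated correlation). The ribonucleotide reductase subunit RRM2 fell 14.1-fold to 2.87 ± 0.28 CPM, CDC45 6.35-fold and CENPU 6.29-fold, and the mitotic genes CDC20, BIRC5 and KIF20A fell 16.4-fold, 16-fold and 14.1-fold. Repair genes fell in 19 of 30 (22 over the list alone; adjusted p = 1.06e-06, 0.00584 with an estimated correlation), with EXO1 down 4.7-fold, POLQ 3.39-fold and FANCA 3.07-fold. Nuclear envelope and chromatin genes fell in 22 of 28 and rose in 1 (22 and 2 over the list alone; adjusted p = 4.91e-11, 0.00522 with an estimated correlation), with UHRF1 down 3.41-fold and the histone methyltransferase EZH2 2.6-fold. Histone genes rose in 20 of 22 (21 over the list alone; adjusted p = 8.7e-15, 0.000138 with an estimated correlation), with H4C8 up 6.37-fold, H2BC4 5-fold and H2BC5 4.57-fold. Of 42 p53 targets 36 rose and 2 fell (36 and 3 over the list alone; adjusted p = 7.98e-26, 4.5e-05 with an estimated correlation), with TNFRSF10C, a decoy TRAIL receptor, up 3.89-fold and ACER2 3.8-fold.

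Interferon-stimulated genes fell in 32 of 46 and rose in 1 (35 and 1 over the list alone), with a median of -0.66 (adjusted p = 4.52e-06; adjusted p = 0.454 with an estimated correlation). OAS1 fell 6.99-fold, CMPK2 4.46-fold and MX1 3.64-fold, MX1 from 214 ± 5.7 to 58.8 ± 1.4 CPM. Secreted SASP factors were 11 up and 14 down of 41 (11 and 15 over the list alone; adjusted p = 0.938), with the growth factor NRG1 up 3.52-fold and CXCL12 and STC1 down 3.09-fold and 2.94-fold. Secreted proteases and inhibitors were 8 up and 11 down of 25 in both counts (adjusted p = 0.259): MMP11 and MMP1 fell 4.93-fold and 3.2-fold and ADAMTS5 rose 2.77-fold. IGF-binding proteins rose in 5 of 6, also over the list alone (adjusted p = 2.47e-06, 0.00584 with an estimated correlation), with IGFBP5 up 2.63-fold to 6340 ± 560 CPM, IGFBP3 2.26-fold and IGFBP7 1.48-fold. Myofibroblast and TGF-beta response genes were 10 up and 4 down of 26 in both counts (adjusted p = 0.0152, 0.0249 with an estimated correlation), with CCN2 up 3.07-fold and POSTN 2.48-fold. Collagens and elastic fibre genes were 24 up and 17 down of 51 (25 and 18 over the list alone; adjusted p = 0.144), with ELN up 2.48-fold and TNC down 4.05-fold.

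Cholesterol genes fell in 20 of 25 (21 over the list alone; adjusted p = 7.33e-10, 0.00584 with an estimated correlation), with INSIG1, FDPS and LSS down 2.1-fold, 1.71-fold and 1.69-fold. Lysosomal genes fell in 29 of 48 and rose in 5 (32 and 7 over the list alone; adjusted p = 1.99e-06, 0.033 with an estimated correlation), with the cholesterol transporter NPC1 down 2.53-fold and the cathepsins CTSS and CTSK 2.12-fold and 2-fold. NRF2 targets rose in 12 of 26 and fell in 5 (14 and 5 over the list alone; adjusted p = 0.00606, 0.033 with an estimated correlation): SLC7A11 rose 3.5-fold and AKR1C2 and AKR1C3 fell 2.86-fold and 2.24-fold. Unfolded protein and integrated stress response genes rose in 19 of 34 and fell in 3 (20 and 3 over the list alone; adjusted p = 1.41e-05, 0.0144 with an estimated correlation), with PSAT1 up 3.38-fold, SESN2 2.45-fold and MTHFD2 2.24-fold. Ribosomal protein genes were 1 up and 7 down of 73 (adjusted p = 0.608; 1 and 6 over the list alone), RPS19 rising 1.33-fold and RPS7 and RPL10 falling 1.29-fold and 1.19-fold. Shelterin and telomere genes were 3 up and 1 down of 16, also over the list alone (adjusted p = 0.893), with TERF2IP up 1.26-fold, STN1 up 1.3-fold and CTC1 down 1.32-fold, a call lost without DOX replicate 2 (adjusted p = 0.077). NRG1, TNFRSF10C, UHRF1, H2BC5, NPC1, MTHFD2, STN1, RPS19, RPL10, PDGFRA and PRRX1 overlap another gene on the same strand and are uncertain. LRATD2, NRCAM and APLP1 completed the largest rises at 6.85-fold, 6.79-fold and 5.7-fold.

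Among the check lists, keratinocyte markers rose in 4 of 9 with none falling (adjusted p = 0.000389, 0.00584 with an estimated correlation). KRT17 rose from 3.28 ± 0.44 to 16 ± 1.6 CPM and CLDN1 from 1.56 ± 0.15 to 7.69 ± 0.57 CPM. Fibroblast identity genes were 3 up and 8 down of 14 (adjusted p = 0.0392; adjusted p = 0.34 with an estimated correlation), with PDGFRA, PRRX1 and VIM down 2.02-fold, 1.75-fold and 1.57-fold. Mitochondrially encoded mRNAs were 4 up and 1 down of 13 (adjusted p = 0.0392; adjusted p = 0.567 with an estimated correlation), MT-ND5 and MT-CO3 rising 1.35-fold and 1.25-fold. MT-ND6 fell 1.62-fold, but without DMSO replicate 1 its log2 fold change was -0.07609 (adjusted p = 0.865), and its call was also lost with DESeq2, with the 10 CPM filter and without DOX replicate 2 or 3 (adjusted p = 0.167, 0.0692, 0.111 and 0.177). The fibroblast identity and mitochondrial calls were lost without genes that overlap on the same strand (adjusted p = 0.181 each) and without single libraries (adjusted p up to 0.0581 and 0.138). Immediate early genes were 5 up and 5 down of 22 (adjusted p = 0.893), with BTG2 up 1.78-fold and NR4A3 and KLF6 down 2.27-fold and 2.09-fold. Endothelial, melanocyte and Schwann, leukocyte, and adipocyte and smooth muscle markers were not called (adjusted p = 0.91, 0.217, 0.259 and 0.826). Each of these lists had the same counts over the list alone, except the endothelial markers with 1 more fall there (3 against 2 of 5).

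The overlap of the P33 and DOX changes was counted next, and the comparisons share no library. Among the 16821 genes 1543 rose in both P33 against P3 and DOX against DMSO, where independent lists would share 971.5, and 1933 fell in both, against 1154. Another 733 rose at P33 and fell with DOX (1194 for independent lists), and 554 did the reverse (939), so 73% of genes that passed in both went the same way. At a 2-fold minimum 328 rose in both and 182 fell in both (91.9 and 38.2 for independent lists). CDKN1A, CDKN2B, SLC7A11 and IGFBP5 rose in both, and MKI67, LMNB1, INSIG1, MMP1 and CXCL12 fell in both. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.308 and a Spearman correlation of 0.304, and without a count filter the Pearson correlation was 0.135. Without the cell cycle, histone, repair and chromatin lists, an alternative chosen after seeing the data, 1523 rose and 1830 fell in both.

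**Figure D3:**
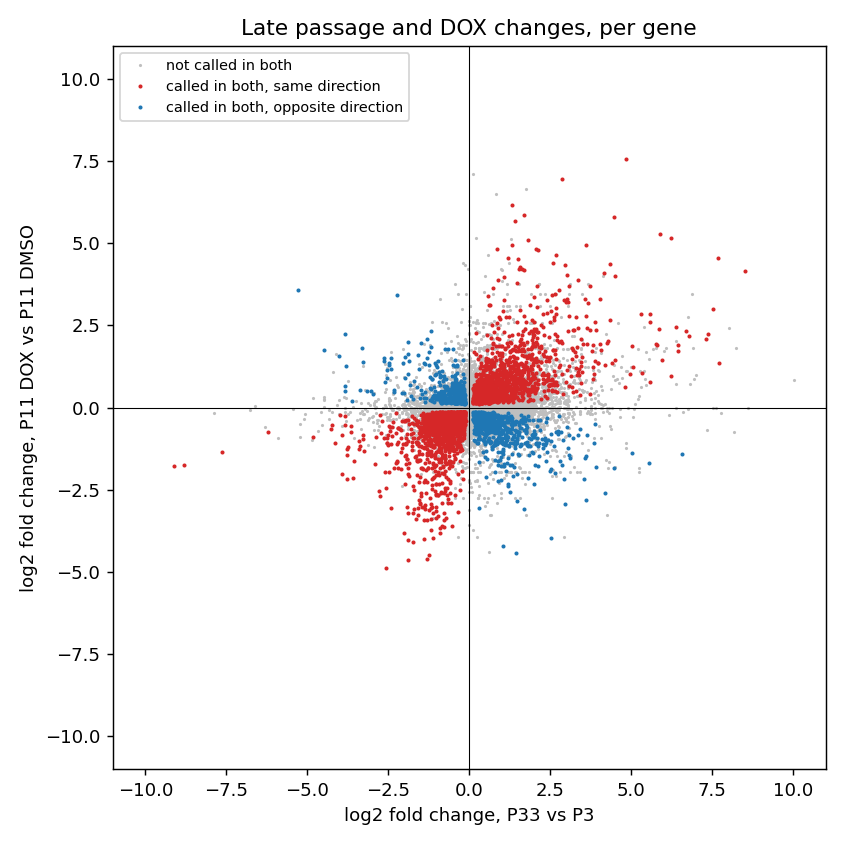
Log2 fold change of each tested gene, apart from those of the Y chromosome and X inactivation, at P33 against P3 (x axis) and with DOX against DMSO (y axis), red where the gene passed in both with the same direction, blue with opposite directions and grey otherwise. The Pearson correlation across all tested genes is 0.308, and 0.135 without a count filter.

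The difference of both effects, DOX minus P33, was tested directly. The myofibroblast and TGF-beta response list, higher for DOX, was the 1 list whose call held with an estimated correlation (adjusted p = 0.00422). That test used P3 as the baseline for P33. Against P11 the list was not called at P33 (11 up and 13 down, camera adjusted p = 0.611). The difference was not tested for lists with P11 as baseline. Interferon-stimulated genes, ribosomal protein genes and SASP factors had the largest median differences among called lists, but their calls were lost (adjusted p = 0.301, 0.234 and 0.301 with an estimated correlation): the first and last rose at P33 and did not rise with DOX, and ribosomal protein mRNAs fell at P33 and were not called with DOX. The P33 calls of these lists were lost as well (adjusted p = 0.323 for interferon-stimulated genes, 0.246 for SASP factors and 0.0706 for ribosomal protein genes with an estimated correlation). SASP factors already stood higher in the DMSO control than in untreated P11 cells, across parts not counted alike. Their median log2 levels against P3 were -0.134 at P11, 0.66 with DMSO and 0.58 with DOX. OAS1 rose from 4.44 ± 1.4 to 53.3 ± 5.3 CPM with passage and fell from 15.3 ± 1.1 to 2.19 ± 0.16 CPM with DOX (log2 difference -6.42, SE 0.444, adjusted p = 1.3e-13). MKI67 fell more with DOX (difference -2.37, SE 0.125) and CDKN1A rose more (1.20, SE 0.0707). Of 16821 genes 8615 differed between the effects, 4343 with the higher value for DOX and 4272 with the lower, but 864 and 1814 at a difference of at least 2-fold. In all 11 lists were called, but 30 of 50 splits of the libraries gave as many, so the number of called lists is not told apart from other splits.

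Of 46 interferon-stimulated genes 39 had a lower DOX effect and none a higher one (40 and 0 over the list alone), with a median difference of -2.13 (adjusted p = 8.1e-14; adjusted p = 0.301 with an estimated correlation). RSAD2 and IFI44L differed by -6.78 and -5.70. Of 73 ribosomal protein genes 67 had a higher DOX effect and none a lower (68 and 0 over the list alone), with a median of 0.90 (adjusted p = 7.64e-27; adjusted p = 0.234 with an estimated correlation), RPS26, RPS28 and RPS18 by 1.74, 1.45 and 1.38. Of 41 SASP factors 26 were lower and 5 higher (27 and 5 over the list alone; adjusted p = 8.21e-05; adjusted p = 0.301 with an estimated correlation). EREG, an EGF receptor ligand, rose from 123 ± 3.8 to 1160 ± 130 CPM at P33 and did not pass with DOX (108 ± 5 CPM with DMSO and 95.6 ± 4.7 with DOX), while INHBA fell at P33 and rose with DOX (difference 3.66, SE 0.115). CXCL8 differed by -5.09. Of 26 myofibroblast and TGF-beta response genes 17 were higher for DOX and 4 lower, also over the list alone (adjusted p = 3.17e-05), the 1 list call that held with an estimated correlation (adjusted p = 0.00422), with POSTN, ANKRD1 and MYL9 at 2.56, 1.79 and 1.70. Among the check lists, adipocyte and smooth muscle markers were 3 higher and none lower of 7, with a median of 0.9164 (adjusted p = 0.0628; adjusted p = 0.301 with an estimated correlation), and passed without a count filter, without P3 replicate 1 and without P33 replicate 1 (adjusted p = 0.0184, 0.0423 and 0.0424).

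Cell cycle lists differed too: 37 of 53 G2 and M phase genes and 22 of 43 S phase genes fell more with DOX, and 8 and 5 less (adjusted p = 1.08e-05 and 0.0176; adjusted p = 0.301 and 0.321 with an estimated correlation). CENPA, UBE2C and GTSE1 differed by -3.36, -2.88 and -2.77, and RRM2, DTL and RAD51AP1 by -2.91, -2.46 and -2.23. Repair genes fell more with DOX in 14 of 30 and less in 1 (adjusted p = 0.0203; adjusted p = 0.301 with an estimated correlation), EXO1, XRCC2 and POLQ by -1.63, -1.23 and -1.16. Of 42 p53 targets 20 were higher for DOX and 9 lower (adjusted p = 0.0336; adjusted p = 0.301 with an estimated correlation and 0.129 without genes that overlap on the same strand): FDXR and CYFIP2 differed by 1.63 and 1.55 and GDF15 by -1.56. Collagens (30 higher and 16 lower of 51), cholesterol genes (13 and 2 of 25) and stress response genes (5 and 19 of 34) were called as well (adjusted p = 0.0423, 0.0234 and 0.0113; adjusted p = 0.564, 0.301 and 0.301 with an estimated correlation), with COL15A1 and MFAP4 at -2.49 and -2.84, ACAT2, NSDHL and MVK at 1.36, 0.88 and 0.69, and ATF3, CEBPB and TRIB3 at -2.80, -2.76 and -2.01. The collagen call was also lost with the replicate block (adjusted p = 0.0526) and without genes that overlap on the same strand or single libraries (adjusted p = 0.774, and up to 0.0682 for the libraries). Over the list alone the lower and higher counts were 37 and 8, 23 and 6, and 14 and 1 for the G2 and M phase, S phase and repair lists, and the higher and lower counts 20 and 9, 30 and 16, 14 and 2, and 6 and 20 for p53 targets, collagens, cholesterol and stress response genes.

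Lists without a called difference still held single genes that differed. Histone genes were 4 higher and 3 lower of 22 (adjusted p = 0.314), H2BC5 at 1.64 and H2BC21 at -0.97, and nuclear envelope genes 13 higher and 9 lower of 28 (adjusted p = 0.326), LMNB1 at -1.26 and LMNA at 1.01. PLAT differed by -3.55 and MMP3 by 1.67 (protease list, adjusted p = 0.841), IGFBP6 by 0.97 and IGFBP2 by -0.94 (IGF-binding proteins, 0.271), and CTSS and CTSO by -2.33 and -1.20 (lysosome, 0.161). AKR1C3 and HMOX1 differed by -2.98 and -1.59 (NRF2 list, adjusted p = 0.114), NHP2, NOP10 and GAR1 by 1.06, 0.98 and 0.82 (telomere list, 0.211, but 0.0411 without a count filter), and COL1A1 and PDGFRA by 1.36 and -1.18 (fibroblast identity, 0.351). In the panel (adjusted p = 0.193) LMNB1, HMGB2, GLB1, IL6, CDKN2B and GDF15 were lower for DOX, HMGB1 and RB1 higher, and CDKN2A and TP53BP1 did not pass. RB1 did not pass with the 10 CPM filter (adjusted p = 0.0615), and CDKN2A passed as higher for DOX without P3 replicate 1, P33 replicate 3 or DOX replicate 3 (adjusted p = 0.0393, 0.0335 and 0.018). Among single genes the largest differences included CDH6, TRIM55 and EPB41L3 at 6.08, 5.06 and 4.34 and SYT7 and LAMP3 at -7.24 and -6.37. WNT2 had no read at P33 and KLHDC7B none at P3, so no size is given for them. CENPA, DTL, CDH6, SYT7 and H2BC5 overlap another gene on the same strand and are uncertain.

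**Figure D4:**
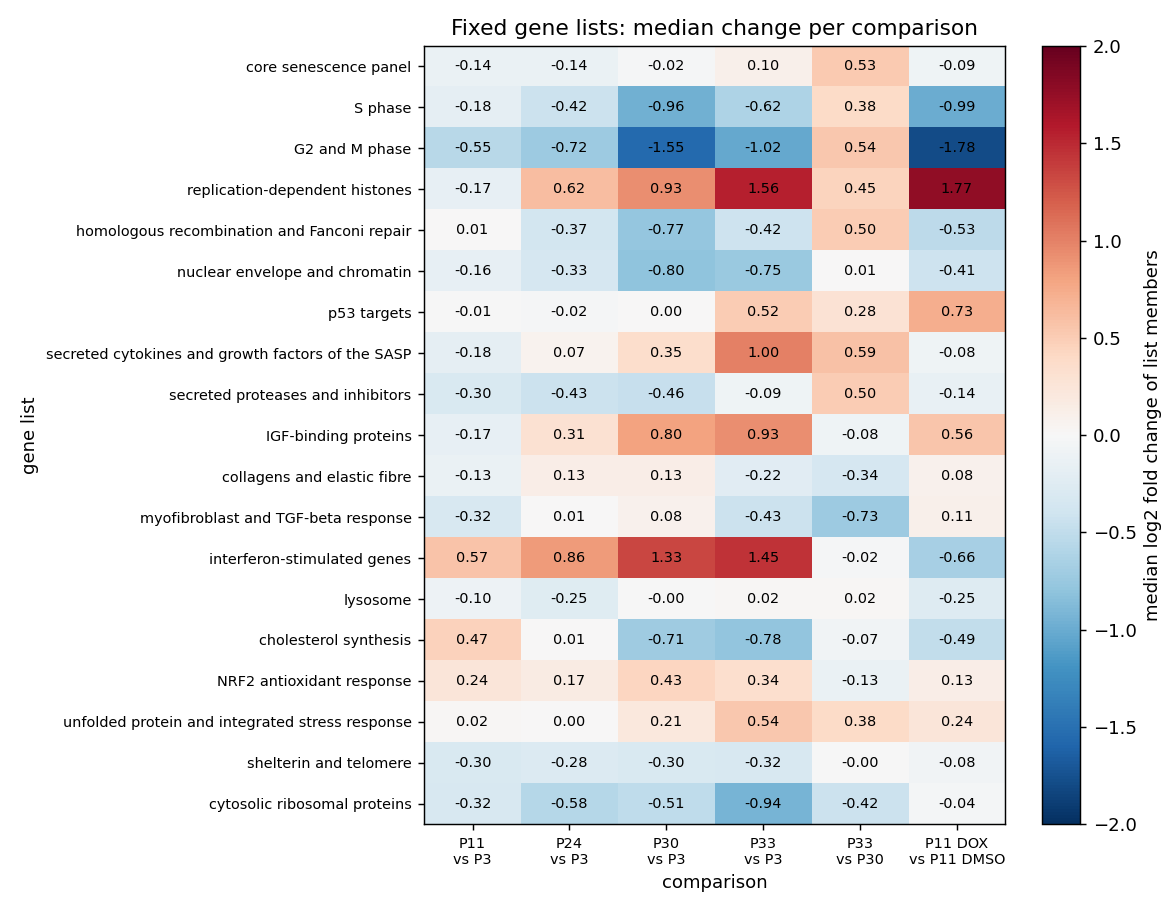
Median log2 fold change (colour and printed value) of 19 gene lists (y axis) in 6 comparisons (x axis). Interferon-stimulated genes have medians of 1.45 at P33 against P3 and -0.66 with DOX, and cytosolic ribosomal protein genes -0.94 and -0.04.

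DMSO cells and untreated P11 cells have the same passage label and neither had DOX, so their comparison shows how far the parts of the series stand apart. It gave 11897 calls, 6137 higher and 5760 lower, more than any other comparison, and 510 of them lie inside another gene on the same strand. Without genes that overlap on the same strand it gave 7193, fewer than the 7722 of P33 against P3. HNRNPA1, CALM2 and OAZ1 had no read at P11 and 734 ± 41, 557 ± 37 and 496 ± 33 CPM with DMSO, at least 13600-fold, 10300-fold and 9170-fold higher, while CLVS1 and C1QTNF3-AMACR were 262-fold (72.2 to 2170) and 214-fold (58.9 to 1770) lower. MSANTD3-TMEFF1 fell 119-fold. MKI67, which has no such overlap, fell from 269 ± 25 to 151 ± 17 CPM, 44 of 53 G2 and M phase genes fell (also over the list alone), and fibroblast identity genes rose in 11 of 14 with PDGFRA, which does overlap another gene, at 738 ± 40 against 81.4 ± 6 CPM (adjusted p = 4.91e-10 and 9.54e-05; adjusted p = 0.257 and 0.246 with an estimated correlation). Ribosomal protein genes rose in 56 of 73 and fell in 9, also over the list alone (adjusted p = 1.2e-07, 0.426 with an estimated correlation). SASP factors gained a call without same-strand overlaps and without a count filter (median 1.148 and 0.9366, camera adjusted p = 0.00863 and 0.0163). IL6, CXCL8 and CXCL12, which fell with DOX, were at 11.58 to 12.97, 2.406 to 2.704 and 646.1 to 717.5 CPM in DMSO libraries. In P11 libraries they were at 4.387 to 6.89, 0.3134 to 0.9357 and 156.5 to 166.6 CPM, while EREG was higher there. No gene wholly inside another on the same strand had a read in any passage library (0 of 9429, against 3950 in the DOX and DMSO libraries). The values of such genes, HNRNPA1 among them, therefore show a difference of counting. CALM2 and OAZ1 had a few reads at other passages (0.1105 CPM in a P30 library and 0.05259 in a P24 library). They are thus not wholly inside another gene. Both stayed at or below 0.1105 CPM in every passage library and at 353.8 to 596.7 CPM in every DOX and DMSO library, a pattern like that of HNRNPA1. Their fold values are therefore not taken as a change of expression, and the cause of their difference was not tested. Overlap on the same strand was not the whole of the difference between the parts, since 66.9% of genes without such an overlap passed, 2135 of them by at least 2-fold. For these genes culture, treatment and other steps of counting cannot be told apart.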

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

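The tests of ribosomal protein mRNAs by length, GC content and baseline, of the chromosome 6 gene clusters, and of library scaling for cell cycle genes were chosen only after the result was seen, the genes used for the ribosomal trends and for every chromosome 6 test were changed after a first value was seen, and so were the number and pool of splits drawn for the difference.

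The DOX effect and the P33 effect differed, by a test of the difference itself, in 11 gene lists. Median log2 differences were -2.131 for interferon-stimulated genes, -1.048 for SASP cytokines and growth factors, -0.7269 for G2 and M phase, -0.4629 for homologous recombination and Fanconi repair, -0.3703 for S phase and -0.2572 for the unfolded protein and integrated stress response. They were 0.9042 for cytosolic ribosomal proteins, 0.8021 for myofibroblast and TGF-beta response, 0.3094 for collagens and elastic fibre, 0.3002 for p53 targets and 0.2929 for cholesterol synthesis. The myofibroblast list was the 1 list of the 11 that also passed with an estimated correlation. Lists were not tested for the difference with P11 as the baseline for P33.

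Ribosomal protein mRNAs were lower at P33 than at P3, with a median of -0.937 over 73 genes. The list call was lost with an estimated correlation (adjusted p = 0.0706 with an estimated correlation). With the length trend of other genes taken off the median was -0.7626, and with the GC trend taken off -0.7606, so neither trend alone accounts for it; both trends together were not tested. The median was -0.5925 against P11, so the P3 libraries alone do not account for it. Passage stays an open explanation, and reads shared with processed pseudogenes were not tested.

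Genes of chromosome 6 were lower at P33 than at P30, by a median of -0.1819 over 825 genes against the other autosomes. Chromosome 21 was next, at -0.1175 over 165 genes (-0.1342 for P33 against P11), and no other autosome lay below -0.01919. The shift was -0.1999 after GC and length trends and -0.1614 for genes beyond 60 Mb, outside the histone and HLA clusters. The smallest shift among the 3 P33 libraries and 3 expression classes was -0.165, and 16 of 16 windows of 10 Mb lay below the other autosomes. Loss of a copy in part of the cells is a candidate explanation, found and tested on the same data, and DNA was not analysed here.

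S phase and G2 and M phase genes were higher at P33 than at P30, list calls that were lost with an estimated correlation (adjusted p = 0.0688 and 0.104 with an estimated correlation). Exchanged labels would place P30 farther from P3. This was scored on 1683 genes called at 2-fold in P24 against P3, with the S phase and G2 and M phase lists left out. Of these, 65.3% were farther from P3 at P33 than at P30, in the direction of P24. The smaller gap between the lowest P33 and the highest P30 library was 0.2864 in mean log2 CPM, so 1 library does not account for it, and the smallest excess over the median of all genes was 0.3816 under TMM and RLE scaling. The growth state of the cultures at harvest was not tested and stays open.

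For comparisons of 3 with 3 libraries, 10 splits exist, too few for a share under 0.05. The real split was the 1 split with as many genes at P11, P24, P30 and P33 against P3 (7825, 9150, 9856 and 11408 genes, highest other 0 each), P24 against P11 (5658, other 30), P30 against P24 (5897, other 0), P33 against P30 (8142, other 2), P33 against P11 (9655, other 0), DOX (6278, other 26) and DMSO against P11 (11897, other 0). Called lists were as many in 3 splits at P11 (10, highest other 11), 3 at P24 (10, other 10), 2 at P30 (12, other 14), 4 at P33 (14, other 15), 1 with DOX (16, other 13) and 4 for DMSO against P11 (9, other 9). For the difference and the overlap 50 of 200 splits were drawn. The real split was the 1 split as large for 8615 genes of the difference (highest other 8174), 1543 that rose in both (other 0), 1933 that fell in both (other 0) and the correlation of 0.3077 (other 0.2309), a share under 0.05. Each other split drawn mixed the groups of at least 1 of the comparisons, so calls in both were not to be expected there, and these splits do not test whether the effects overlap or differ beyond chance. As many lists as the real 11 were called in 30 of 50 splits (highest other 15), so chance is not excluded for the number of called lists in the difference.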

How the results depend on the processing

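The alternatives without same-strand overlaps, without mitochondrial genes and without the cell cycle lists were chosen only after the result was seen. Of 321 values of counts, overlaps and correlation, 289 stayed within the bounds set for them and 32 moved. Of 4686 values of single genes 4620 kept direction and side of the threshold, 45 lost and 6 gained a call and 15 changed direction; of 2234 list values these were 2069, 82, 39 and 44. Except where named, the cause was not tested.

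With a 2-fold minimum, which itself leaves fewer genes, counts in the order of comparisons given above were 997, 1693, 2585, 3556, 922, 1118, 1695, 2474, 1219, 4443 and 2678. With an estimated correlation called lists numbered 3 at P11, 0 at P24, 7 at P30 and 9 at P33 against P3, 0 for DMSO against P11 and 1 for the difference. Without a count filter 18 lists were called at P11 against P3 and the correlation of P33 and DOX fold changes was 0.135. With the 10 CPM filter, which tests fewer genes, 7577 genes passed at P33 against P3 and 7757 for DMSO against P11, 1288 fell in both and the correlation was 0.3237. Without same-strand overlaps, again with fewer genes tested, counts were 5198 for P11 against P3, 3736 for P24 against P11, 5416 for P33 against P30 and 7193 for DMSO against P11, and the correlation was 0.3345. With P11 as baseline the correlation was 0.3444, and with 1 library left out it ran from 0.2843 to 0.3147.

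The replicate numbers do not pair the samples: over 63 pairs with the same number the correlation of deviations ran from -0.0772 to 0.0415, and 7 of 21 libraries correlated best with their own number. With the replicate block 11377 genes passed at P33 against P3, 6221 with DOX and 8578 for the difference, with 14, 16 and 10 lists. Without a count filter collagens, lysosome and shelterin lists were called as lower at P33 against P3 (adjusted p = 0.0463, 0.0436 and 0.0436), as were proteases and ribosomal proteins with DOX (adjusted p = 0.00626 and 0.0228). The block ended 2 list calls, collagens in the difference and IGF-binding proteins for DMSO against P11 (adjusted p = 0.0526 and 0.0542).

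Changes of direction, by the sign of a gene's value or the direction of a list's test, were in genes and lists that did not pass, except that fibroblast identity at P30 against P3 passed as lower without a count filter (-0.1519, adjusted p = 0.0314). For TP53BP1 the difference was -0.007377 with RLE factors, -0.007183 with DESeq2, -0.09332 with the 10 CPM filter and -0.04595 without same-strand overlaps, and for RB1 with DOX 0.0002795 with the 10 CPM filter. Medians without a count filter were, at P11 against P3, -0.006347 for repair, 0.004335 for the unfolded protein response and -0.03791 for keratinocyte markers; at P24, 0.05521 for SASP factors, -0.006116 for the unfolded protein response, -0.1372 for fibroblast identity and 0.1734 for adipocyte markers. They were -0.01418 for p53 targets and 0 for keratinocyte markers at P30, 0.3723 for melanocyte markers at P33, -0.01164, 0.3739 and 0.9303 for shelterin, endothelial and melanocyte lists with DOX, 0.0244 for shelterin for DMSO against P11, and 0.03301 for melanocyte markers in the difference. Without same-strand overlaps they were 0.03192 and -0.05457 for fibroblast identity and melanocyte markers at P11, 0.113 and -0.2822 for SASP factors and adipocyte markers at P24, -0.126 for adipocyte markers at P30, -0.07123 and 0.1783 for proteases and melanocyte markers at P33, -0.03897 and -0.7776 for collagens and adipocyte markers with DOX, and 0.1233 for the myofibroblast list for DMSO against P11.

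With each library left out in turn, ranges for results that changed direction were -0.04524 to 0.06514 for the TP53BP1 difference, -0.2063 to 0.04565 for CDKN2A and -0.0718 to 0.04157 for RB1 with DOX. For lists with DOX they were -0.2176 to -0.03889 for SASP factors, -0.07502 to 0.01005 for ribosomal proteins, -0.5294 to -0.2132 for endothelial markers and -0.1169 to -0.006442 for shelterin. At P11 against P3 they were -0.2323 to 0.03124 for melanocyte markers, -0.03206 to 0.04136 for fibroblast identity and -0.01024 to 0.04032 for repair. At P24 against P3 they were -0.03234 to 0.008578 for p53 targets, -0.1253 to -0.00223 for adipocyte markers, -0.1366 to 0.2002 for SASP factors and -0.05135 to 0.02651 for the myofibroblast list, and at P33 -0.2587 to 0.0001756 for melanocyte markers.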

Other observations

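The tests of gene families and of the region around ABCB1 were all chosen only after the result was seen.

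Among 161 groups of genes with a shared name stem and at least 10 members, 25 were called at P33 against P3, 2 of them with an estimated correlation. These were genes whose symbols begin with EIF, translation initiation factors together with kinases and binding proteins that act on them, with 40 of 53 lower and 7 higher, and genes whose symbols begin with POLR, RNA polymerase subunits and related genes, with 26 of 33 lower and 3 higher (adjusted p = 0.0396 each with an estimated correlation). The EIF group holds EIF4A1, at 0 CPM in all passage groups, and the near-copies EIF3C and EIF3CL (log2 fold changes -2.25 and -2.649). The POLR group counts POLR2J3 more than once, with an entry at 0 CPM in all passage groups. Genes are not independent replicates, and the groups were not fixed beforehand. The P3 libraries stood apart in make-up, and these groups were not tested with P11 as the baseline. How much of their fall came before P11 was therefore not settled.

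ABCB1 and RUNDC3B, which overlap on opposite strands, rose along the passages, ABCB1 from 0.532 ± 0.14 CPM at P3 to 48 ± 5.6 CPM at P33. The strand setting of the counting is not given in the sources used here. In the passage libraries 4260 genes inside an opposite-strand gene had reads, and 0 of 9429 inside a same-strand gene did. These values argue against counting without regard to strand in those libraries. Reads carried to the wrong strand were not measured, so RUNDC3B was not taken as a separate observation. A gain of copies of the region could raise neighbours too: the 10 other tested genes within 2 Mb had a median log2 fold change of 0.4758, 6 rose and 2 fell. The highest of the 10 was 3.424, in ADAM22 (SE 0.209), against 6.453 for ABCB1 and 5.94 for RUNDC3B, and of the genes at either side ABCB4, next to ABCB1, was at 1.838 (SE 0.0975) and SLC25A40, next to RUNDC3B, at -0.05688 (SE 0.0966), so a gain of all these genes is excluded as the whole cause. A gain limited to ABCB1 and RUNDC3B, or a smaller gain, which could take in ABCB4, beside another cause, was not tested and stays open.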
